A study of Mus musculus with 21 samples.

How the data were processed

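MicroRNAs were sequenced from the left ventricular myocardium of 21 C57BL/6J mice, 1 library per mouse. The groups were sham surgery (Sham, 5 mice), transverse aortic constriction, a surgery that overloads the left ventricle with pressure (TAC, 5 mice), TAC with the PDE5A inhibitor sildenafil (TAC+PDE5A-I, 5 mice) and TAC with the PDE9A inhibitor PF-04449613 (TAC+PDE9A-I, 6 mice). Phosphodiesterases 5A and 9A break down the second messenger cyclic GMP. Both drugs were given for 4 weeks, starting 1 week after surgery, so the drug groups were matched in time. The doses are not given in the sources used here. RNA came from frozen tissue and went into Illumina small RNA libraries.

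The deposited table holds raw read counts per mature microRNA for the 21 libraries, which the authors left unnormalised. The submitters list CASAVA 1.8.4, cutadapt 1.8, Bowtie 1.1.1 and DESeq 1.26.0 without their roles, and the genome build and the microRNA annotation behind the counts are not given in the sources used here. Of 25958 lines in the table, 1903 carry a microRNA name and 24055 are blank. No value equals 1 and the smallest value above 0 is 2. Near-identical microRNAs share 12 joined names, such as miR-199a-3p/miR-199b-3p. Reads of close relatives (miR-486a and miR-486b, members of the let-7, miR-29 and miR-30 families, miR-125a and miR-125b, miR-101c, miR-378c) can be assigned to one another, so a value for 1 member of such a family carries that uncertainty.

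A total of 832 microRNAs had a count in any library. Total counts ran from 1205417 to 8497792 per library. A count of 0 is compatible with up to 3 counts, which is 0.353 CPM (counts scaled by the library total) in the deepest library and 2.489 CPM in the shallowest. Reads without molecular identifiers are not independent molecules, so these limits cover counting error only. Where every library of a group was at 0, the fold is given as a lower bound against 3 counts per library.

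Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 561 microRNAs that passed filterByExpr by group were scaled with TMM and fitted with a robust quasi-likelihood model of all 4 groups, with 17 residual degrees of freedom before moderation. Each comparison used the quasi-likelihood F test, and a microRNA was called at a Benjamini-Hochberg adjusted p under 0.05 over the 561. Levels are TMM-scaled CPM, given as mean ± SD with n mice, and log2 fold changes carry ± their standard error (SE). A prior count of 2 was used for log2 CPM. TAC+PDE5A-I against TAC+PDE9A-I is also the test of the difference of the drug effects, since both share the TAC control, and its 95% intervals are intervals of that difference.

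The groups, the 4 main comparisons, the test, 17 lists of microRNAs, 18 microRNAs to be named whatever their result and the rule for further names were fixed before the data were examined. The rule took, per comparison, the 8 higher and the 8 lower called microRNAs with the smallest p among those with a mean of at least 10 CPM (the 3 with the smallest p where fewer than 3 passed) and up to 4 members of each list that passed its set test. MicroRNAs named outside this rule were chosen after their values were seen: miR-7689-3p, miR-140-3p, miR-27b-3p, miR-208a-5p, miR-486a-5p and miR-486b-5p, miR-351-3p, miR-33-5p, miR-130a-5p, let-7f-2-3p, miR-99b-5p, miR-378b, miR-101a-3p, miR-101b-3p and the examples given for lists that did not pass.

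The lists were microRNAs that textbook accounts give as raised in cardiac hypertrophy, those given as lowered, muscle microRNAs, the miR-29, miR-30, let-7 and miR-15/16 families, the miR-17-92 cluster with its paralogs, the miR-322/503 and miR-212/132 clusters, the miR-199/214 group of stromal cells, the imprinted Dlk1-Dio3 cluster, and markers of vascular smooth muscle, endothelium, leukocytes, erythroid cells and other tissues. The lists overlap: the raised list contains the miR-199/214 group and the miR-212/132 cluster, and the lowered list contains the miR-29 and miR-30 families. Heart muscle itself expresses members of several marker lists. Lists were tested with camera in limma 3.58.1, which compares a list with all other microRNAs at a preset correlation of 0.01, and again with an estimated correlation. They were also tested with fry. The PValue of fry tests whether a list moves on balance one way and its Mixed value tests for change in either direction, and neither compares the list with other microRNAs. All p-values of set tests were adjusted over the 17 lists of a comparison, or over 16 with the GC correction, where the erythroid list had too few members with a GC value to be tested.

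Shares of counts and totals per library were compared with two-sided exact permutation tests (252 or 462 arrangements) and adjusted over 66 tests. Similarity of fold changes was computed across microRNAs, which are not independent replicates. The drug comparisons share the TAC libraries with TAC against Sham. Slopes were therefore set against 1000 simulations with no TAC effect and no drug effect, and against 20 fits on 10 splits of the TAC libraries.

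GC content of the mature arms was estimated from the GRCm38 sequence of hairpins matched by name in GENCODE M21, folded with RNAfold 2.7.2, with a window of 22 nucleotides per arm and a loop centre of 8 nucleotides to either side. The windows were settled on a second attempt by their match to known mature sequences, not by any result, and the values are approximate. Of 306 microRNAs with a mean of at least 10 CPM, 285 had such a value, and 305 of the 306 passed the filter, 284 of them with a GC value. Positions of hairpins are from the same annotation by name and do not speak for the build used by the submitters.

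The alternatives fixed with the comparisons were DESeq2 size factors, total counts and upper-quartile factors in the edgeR fit, no filter, a minimum mean of 10 CPM, the Wald test of DESeq2 1.42.0, limma voom, a fit of the 2 compared groups only, the replicate number as a replicate block, the range of the ear tag number (100s, 500s or 600s) as a covariate, and leaving out each library in turn. Chosen after seeing the data were a per-library correction for arm GC (loess, span 0.75, entered as an offset), leaving out the 4 libraries under 2000000 counts, thinning all libraries to 1205417 counts, and a fit of the 2 compared groups without the libraries under 2000000 counts. The pipeline was tested on simulated data built on the real depths, with true changes of 2-fold and 4-fold. It recovered 34.1% to 50.6% of 2-fold changes and 71.6% to 78.5% of 4-fold changes, and 0.909% to 1.82% of unchanged microRNAs were called. Each simulation changed a large part of the microRNAs. With fewer true changes the adjustment of p is stricter and recovery can be lower. With a simulated GC trend in the TAC+PDE5A-I libraries, 47.1% of unchanged microRNAs were called without the GC correction and 1.67% with it. This trend was built from the same estimated GC values that the correction uses. It therefore does not test how the correction copes with errors in those values.

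Replicate numbers did not pair the mice. The deviations of 30 same-number pairs from their group means had a median r of -0.057 across microRNAs, and 4 of 21 libraries were closest to a library of their own number. Ear tag ranges were spread unevenly over the groups, and neither a sequencing date nor a library batch is given. All 21 libraries were used. Preparation and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.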

Results

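Mature microRNAs were counted by sequencing in left ventricular myocardium of 21 mice: 5 after sham surgery, 5 after TAC, 5 after TAC with sildenafil and 6 after TAC with PF-04449613. Total counts were 3766517 to 7490436 per Sham library and 5373960 to 8497792 per TAC library. The TAC+PDE5A-I libraries held 1205417 to 3969716 counts. In TAC+PDE9A-I, replicate 5 held 1546318 counts and the other 5 libraries held 4785164 to 7532591. The microRNA with the largest share in Sham was miR-22-3p, with 18.8% ± 1.25 of counts (SD, n = 5), followed by the muscle microRNA miR-133a-3p with 13.8% ± 0.838 and by miR-486b-5p with 10.5% ± 1.12. The count-weighted GC content of the microRNA arms was 48.3% ± 0.361 in Sham (n = 5), 48.2% ± 0.408 in TAC (n = 5) and 52.1% ± 2.07 in TAC+PDE5A-I (n = 5). It was 52.9% in TAC+PDE9A-I 5 and 47.2% to 48.6% in the other 5 libraries of that group. Of the variance in log2 CPM, 66.4% lay on a first principal component on which the 5 TAC+PDE5A-I libraries scored 5.53 to 39.0 and TAC+PDE9A-I 5 scored 27.6, while every other library had a negative score.

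**Figure D1:**
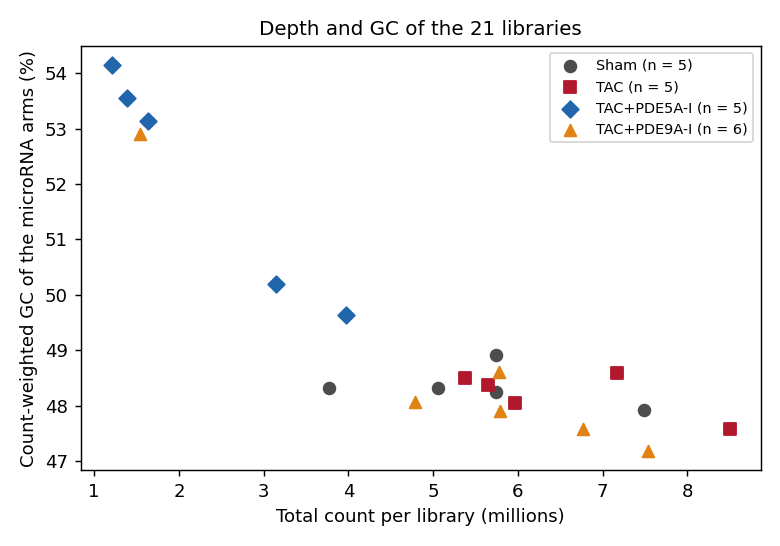
Total count of each of the 21 libraries (x axis) against the count-weighted GC content of its microRNA arms (y axis, percent), with groups by colour and shape. The 5 TAC+PDE5A-I libraries and TAC+PDE9A-I 5 have a GC content above every other library, and the 4 of them under 2000000 counts lie at 52.9% to 54.1%.

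TAC against Sham asked which cardiac microRNAs respond to pressure overload. The largest change among abundant microRNAs was in miR-208b-3p, which lies in an intron of the gene for the slow, fetal-type myosin heavy chain Myh7 (GRCm38 chromosome 14, 54975700 to 54975776). It rose 17.5-fold, from 153 ± 25.8 CPM in Sham (SD, n = 5) to 2681 ± 1195 CPM in TAC (n = 5), a log2 fold change of 4.13 ± 0.68 (SE, adjusted p = 0.00172). The other arm of its hairpin, miR-208b-5p, and miR-7689-3p had no count in any Sham library and were at least 5.29-fold and at least 6.05-fold higher in TAC (adjusted p = 0.0114 and 0.00172). Of the miR-199/miR-214 group, known from fibroblasts and made in part from 1 transcript on chromosome 1, 3 of 5 members rose: miR-199a-5p 3.83-fold, miR-214-3p 3.48-fold and miR-214-5p 3.37-fold.

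Further microRNAs that rose were miR-1247-5p (4.61-fold, log2 2.20 ± 0.49, adjusted p = 0.0208), miR-6944-3p (4.59-fold, 2.20 ± 0.48, adjusted p = 0.0208), miR-34c-5p, a target of the tumour suppressor p53 (4.13-fold, 2.04 ± 0.48, adjusted p = 0.0253), and miR-140-3p (2.13-fold, 1.09 ± 0.28, adjusted p = 0.0429). miR-127-3p and miR-300-3p, from the imprinted Dlk1-Dio3 cluster on chromosome 12, rose 2.26-fold and 1.91-fold (adjusted p = 0.0349 and 0.0374). A single microRNA fell: miR-9-5p, best known from neurons, was 2.31-fold lower, at 12.2 ± 3.65 CPM in TAC against 28.2 ± 8.01 CPM in Sham (n = 5 each, adjusted p = 0.0429). Among the next lower ones by p, miR-378c and miR-338-3p had log2 fold changes of -0.74 ± 0.21 and -0.90 ± 0.25 and did not pass (adjusted p = 0.0608 for each). miR-21a-5p, widely described in fibrotic hearts, measured 9222 ± 4621 CPM in TAC and 2759 ± 157 CPM in Sham, a 3.34-fold difference that did not pass in the fit of all 4 groups (adjusted p = 0.21) but did in a fit of Sham and TAC alone (adjusted p = 0.000754). The same held for miR-146b-5p (3.05-fold, adjusted p = 0.104, and 0.00686 in the fit of the 2 groups). The heart microRNAs miR-1a-3p, miR-133a-3p, miR-208a-3p and miR-499-5p had log2 fold changes of -0.64 ± 0.83, -0.51 ± 0.25, -0.72 ± 0.71 and -0.84 ± 0.67 and did not pass.

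**Figure D2:**
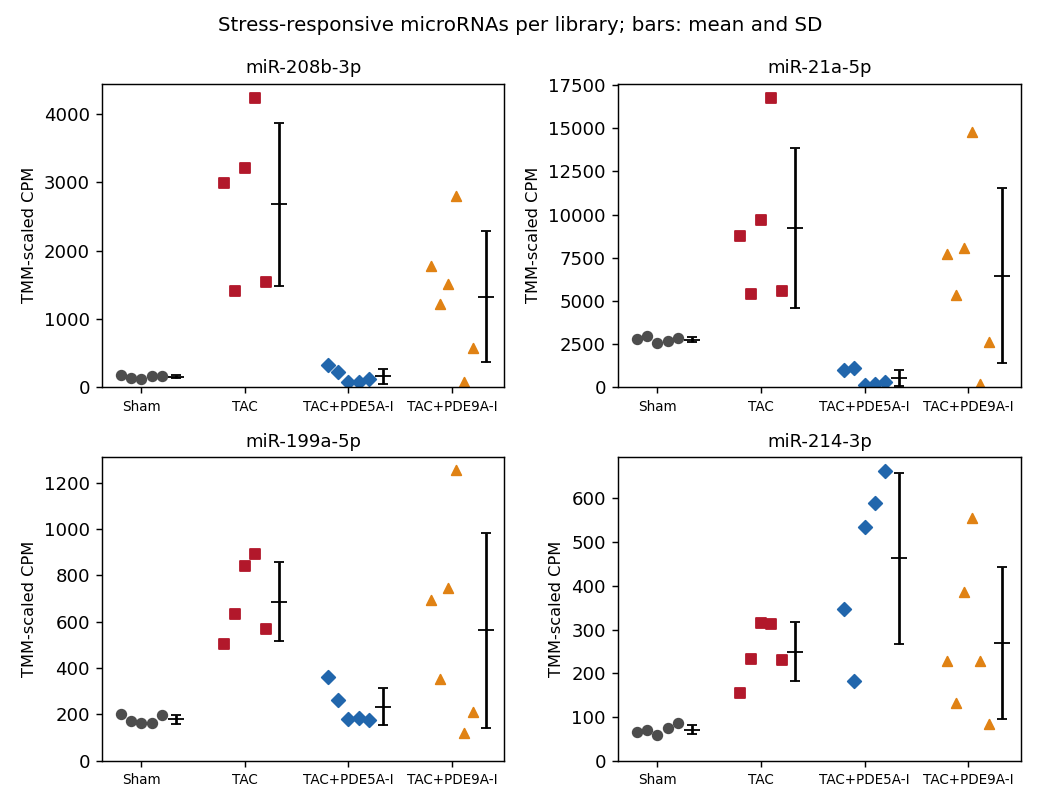
TMM-scaled CPM of 4 microRNAs in each library (points) by group, with mean and SD (bars; n = 5, 5, 5 and 6). miR-208b-3p, miR-199a-5p and miR-214-3p were higher in all 5 TAC libraries than in any Sham library, and TAC+PDE9A-I 5 is the lowest point of its group for miR-208b-3p, miR-21a-5p and miR-199a-5p.

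By list, 6 of 31 measured microRNAs of the list given as raised in hypertrophy rose, 0 fell and 25 did not pass, with a median log2 fold change of 0.61. Adjusted over the list alone, 13 rose. The list lay above the other microRNAs in camera (adjusted p = 8.35e-09; adjusted p = 0.136 with an estimated correlation). Of the miR-199/miR-214 group, 3 of 5 rose and 2 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 4.80e-06; adjusted p = 0.136 with an estimated correlation). The fourth example, miR-199a-3p/miR-199b-3p, had 5856 ± 979 CPM in TAC and 2103 ± 172 CPM in Sham (adjusted p = 0.143). As a share of all counts the group took 0.703% ± 0.137 in TAC and 0.218% ± 0.0232 in Sham (n = 5 each, two-sided exact permutation p = 0.00794, the smallest this design can give; 0.0524 adjusted over 66 tests). Of the Dlk1-Dio3 cluster, 2 of 57 rose, 55 did not pass, and 2 rose adjusted over the list alone (median 0.49; camera adjusted p = 2.93e-06; adjusted p = 0.171 with an estimated correlation). Its next members, miR-431-5p and miR-541-5p, had log2 fold changes of 0.83 ± 0.25 and 0.80 ± 0.25 (adjusted p = 0.0888 and 0.0951).

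Lists given as lowered lay lower in camera at the preset correlation only, without a call over all microRNAs. The PValue of fry did not pass for the lowered list (adjusted p = 0.0570), the miR-30 family (0.0570) or the miR-29 family (0.237). Of the lists above, it passed for the raised list (0.0144) and the miR-199/miR-214 group (0.0127), and not for the Dlk1-Dio3 cluster (0.0574). Of 36 measured microRNAs of the lowered list, 0 passed over all microRNAs and 0 adjusted over the list alone (median -0.50; camera adjusted p = 1.15e-07; adjusted p = 0.171 with an estimated correlation). Examples are miR-30c-1-3p (-0.83 ± 0.23, adjusted p = 0.0608), miR-133b-3p (-0.65 ± 0.23) and miR-378a-3p (-0.49 ± 0.18). The miR-30 family had 0 of 11 called and 4 lower adjusted over the list alone (median -0.66; camera adjusted p = 0.000192; adjusted p = 0.226 with an estimated correlation). The miR-29 family, which targets collagens, had 0 of 7 called and 0 adjusted over the list alone (median -0.52; camera adjusted p = 0.0294; adjusted p = 0.525 with an estimated correlation; camera adjusted p = 0.172 with the GC correction, which did not pass), with miR-29a-3p at -0.44 ± 0.21 and miR-29b-3p at -0.26 ± 0.43. Of 17 muscle microRNAs, 2 rose, the 2 arms of miR-208b, and 15 did not pass, and 2 rose adjusted over the list alone. Their median was -0.51 and their mean 0.22, and the camera test pointed down without passing (adjusted p = 0.462). No member was called in the let-7 family (21 measured, median -0.24), the miR-17-92 cluster and paralogs (17, -0.21), the miR-15/miR-16 family (12, 0.10), the miR-322/miR-503 cluster (11), the miR-212/miR-132 cluster (4, 0.22) or the markers of vascular smooth muscle (4), endothelium (4, -0.26), leukocytes (10, -0.17) and erythroid cells (3, -0.57), with camera adjusted p of 0.329 to 0.941. Adjusted over the list alone, 2 members of the miR-15/miR-16 family rose. The medians of the miR-322/miR-503 cluster (-0.05, or -0.00468 with 1 member at its bound) and of the smooth muscle markers (-0.05) turned to 0.09 and 0.13 with scaling by total counts. Of 12 markers of other tissues, 1 fell (miR-9-5p, also adjusted over the list alone) and 11 did not pass (median -0.36, camera adjusted p = 0.136).

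In all, 12 microRNAs rose and 1 fell of 561 tested by edgeR. The 2 groups did not overlap for 95 microRNAs (16.9%), where chance gives 0.794%. Scaling by total counts moved the median log2 fold change of all microRNAs from -0.08 to 0.09. The count of higher microRNAs fell to 4, 7, 4, 3 and 4 without Sham 1, Sham 2, Sham 3, Sham 4 or TAC 4, while miR-208b-3p passed without any 1 library. The calls of miR-199a-5p, miR-214-3p and miR-1247-5p were lost without Sham 1, 2, 3 or 4 or TAC 4 (adjusted p = 0.0504 to 0.0777), that of miR-214-5p without Sham 4 (0.0529), that of miR-6944-3p without Sham 1, 3 or 4 or TAC 4 (0.0595 to 0.0727), those of miR-34c-5p and miR-127-3p without Sham 1, 2, 3 or 4 or some TAC libraries (0.0504 to 0.128), and those of miR-300-3p without any 1 library but TAC 2 and of miR-9-5p without any but TAC 1 (0.0504 to 0.181). The higher count was 75, with 23 lower, in a fit of Sham and TAC alone, which keeps the drug libraries out of the spread, scaling and filter. It was 4 with the ear tag range as a covariate. All 11 called microRNAs named by the rule had the same direction within the ear tag 100s (2 TAC, 3 Sham) and 600s (2 and 2). As they were called on these same libraries, this is no separate test of an ear tag effect.

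TAC+PDE5A-I against TAC asked how sildenafil changed the microRNAs of the overloaded heart. In the 5 TAC+PDE5A-I libraries, miR-208b-3p fell 16.8-fold, to 159 ± 109 CPM (n = 5; log2 -4.07 ± 0.68, adjusted p = 0.000453), and miR-21a-5p fell 17.4-fold, from 9222 ± 4621 to 530 ± 475 CPM (log2 -4.12 ± 0.80, adjusted p = 0.0013). miR-208a-3p, from an intron of Myh6, fell 9.94-fold, miR-499-5p, from an intron of Myh7b, fell 5.17-fold and miR-199a-5p fell 2.94-fold (adjusted p = 0.00307, 0.0114 and 0.00881). With the GC correction these falls were smaller for miR-208b-3p (log2 -1.50 ± 0.42), miR-21a-5p (-1.85 ± 0.45), miR-208a-3p (-1.36 ± 0.30) and miR-499-5p (-1.14 ± 0.39), about the same for miR-199a-5p (-1.59 ± 0.42), and all 5 passed. Without the correction, the other arm of the miR-208a hairpin, miR-208a-5p, rose (log2 1.57 ± 0.34, adjusted p = 0.00195). The fall of miR-208a-3p therefore does not stand for its whole hairpin. Of the muscle pair miR-1a and miR-133a, which share their primary transcripts, miR-1a-3p fell 10.6-fold (4196 ± 1025 to 395 ± 482 CPM, adjusted p = 0.00632) and miR-133a-3p rose 1.76-fold (107542 ± 28271 to 189579 ± 50629 CPM, adjusted p = 0.0143). The call of miR-1a-3p ended with the GC correction, which moved its log2 fold change from -3.41 ± 0.90 to -0.16 ± 0.23, and miR-133a-3p lost its call without TAC 3 or TAC+PDE5A-I 3, 4 or 5, so the opposite movement of the pair is not secure. These values moved together with the state of the libraries: the fold changes followed the GC content of the microRNA arms across 284 microRNAs (Spearman rho = 0.729, against 0.129 for TAC against Sham), and total counts averaged 2268530 in TAC+PDE5A-I and 6531290 in TAC (two-sided exact permutation p = 0.00794, 0.0524 adjusted over 66 tests).

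The largest fall was that of miR-101c, which had 941 ± 149 CPM in TAC (n = 5) and no count in any TAC+PDE5A-I library, at least 574-fold lower (adjusted p = 0.000181). Its relatives miR-101a-3p and miR-101b-3p fell by 4.38 ± 0.95 and 3.39 ± 0.70 on the log2 scale. miR-144-3p of erythroid cells fell 28.7-fold, miR-142a-5p of leukocytes 22.9-fold, miR-136-5p of the Dlk1-Dio3 cluster 20.3-fold, miR-190a-5p 11.1-fold, miR-340-5p 7.37-fold and miR-148a-3p 6.94-fold (adjusted p from 0.000181 to 0.000872). With the GC correction miR-144-3p (-1.70 ± 0.72) did not pass, and miR-190a-5p and miR-340-5p turned to 0.51 ± 0.49 and 1.01 ± 0.47 (adjusted p = 0.493 and 0.104). let-7f-2-3p, miR-130a-5p and miR-33-5p also had no count under sildenafil and were at least 30.9-fold, 8.92-fold and 4.42-fold lower. Among the microRNAs that rose, miR-501-3p was 3.39-fold higher (68.9 ± 23.5 against 20.2 ± 1.5 CPM, log2 1.76 ± 0.25, adjusted p = 0.000181) and miR-125a-5p 2.64-fold higher (14644 ± 4731 against 5548 ± 1036 CPM, log2 1.40 ± 0.24, adjusted p = 0.000593). miR-324-3p, let-7d-3p, miR-700-5p, miR-874-3p, miR-125a-3p and miR-361-3p rose 1.92-fold to 2.60-fold, of which miR-324-3p and miR-874-3p turned to -0.03 ± 0.15 and -0.31 ± 0.29 with the GC correction (adjusted p = 0.926 and 0.480). miR-351-3p, absent from all TAC libraries, was at least 10.9-fold higher (adjusted p = 0.0124). Of the other microRNAs fixed for naming, miR-29b-3p fell 5.92-fold, miR-146b-5p 4.15-fold, miR-142a-3p 8.43-fold, miR-451a 3.93-fold and miR-30a-5p 2.51-fold. miR-214-3p (0.89 ± 0.40), miR-29a-3p (-0.41 ± 0.21), miR-126a-3p (-1.12 ± 0.57), miR-132-3p (0.46 ± 0.28), miR-34a-5p (0.42 ± 0.19) and miR-212-5p (0.01 ± 0.28) did not pass.

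**Figure D3:**
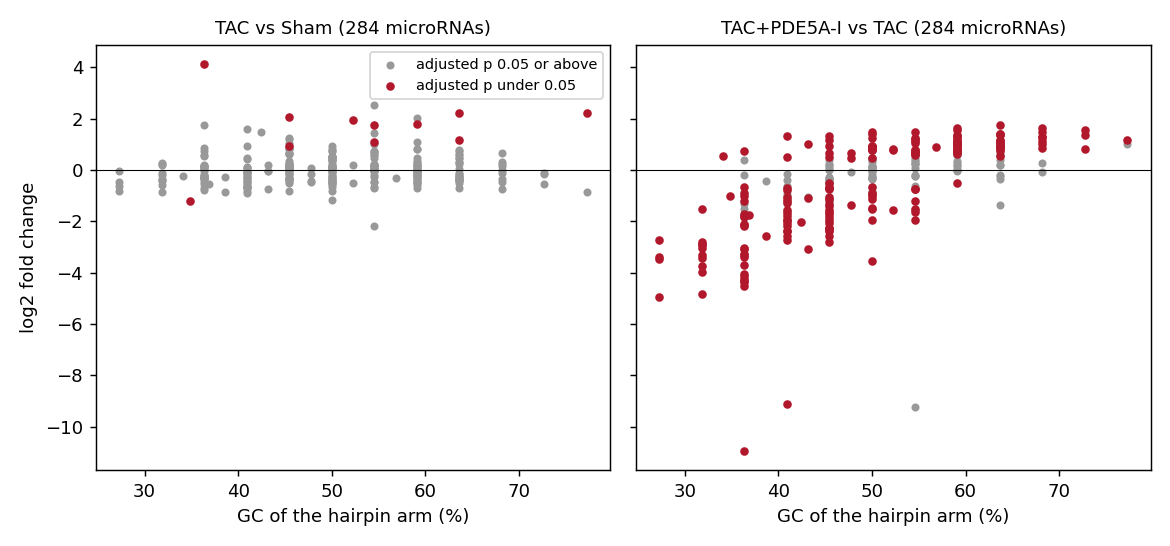
Log2 fold change (y axis) against the GC content of the hairpin arm in percent (x axis) for 284 microRNAs with a mean of at least 10 CPM, in TAC against Sham (left) and TAC+PDE5A-I against TAC (right); red points passed the test. The Spearman rho is 0.129 on the left and 0.729 on the right.

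All lists had members that fell or rose under sildenafil against TAC, and no list stood apart from the other microRNAs in camera (lowest adjusted p = 0.166). With the GC correction the lowered list (adjusted p = 0.00360), the let-7 family (0.0205), the miR-29 family (0.0387) and the miR-30 family (0.0387) lay higher, and none passed with an estimated correlation (0.805). In the list given as raised in hypertrophy, 12 of 31 fell, 2 rose and 17 did not pass (median -0.77). In the lowered list 13 of 36 fell, 8 rose and 15 did not pass (median -0.38), a median that turned to 0.05 with upper-quartile scaling and 0.12 with the GC correction. Of 17 muscle microRNAs 7 fell, 4 rose and 6 did not pass (median -0.91, or -0.87 with 1 member at its bound). Adjusted over the list alone, 15 of the lowered list, 6 of the miR-30 family and 7 of the miR-15/miR-16 family fell, 4 leukocyte markers rose, and the counts of the lists not named here for this were those over all microRNAs. Of the miR-199/miR-214 group 3 of 5 fell and 2 did not pass, adjusted over the list alone 4 fell and 1 rose, and miR-214-3p had the opposite sign to the other 4. Of the Dlk1-Dio3 cluster 16 of 57 fell, 5 rose and 36 did not pass (median -0.96, or -0.50 with 9 members at their bounds). The endothelial markers had 3 of 4 lower and 1 not passing, among them miR-126a-5p (27641 ± 7358 to 2839 ± 3338 CPM), and all 3 erythroid markers fell. The smooth muscle markers had 2 of 4 lower and 1 higher: miR-143-3p fell 5.18-fold and miR-145a-3p 5.96-fold, while the other arm miR-145a-5p rose 1.59-fold. Leukocyte markers split into 3 higher, 3 lower and 4 not passing (median -0.14, test direction up, and a median of 0.31 with upper-quartile scaling and 0.30 with the GC correction).

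Of the let-7 family 8 of 21 rose, 9 fell and 4 did not pass (median -0.66, or 0.76 with the GC correction). let-7b-5p rose (log2 1.32 ± 0.32) and let-7f-5p fell 2.90-fold, but was higher with the GC correction (1.55 ± 0.41, adjusted p = 0.00654). In the miR-17-92 cluster and paralogs 6 of 17 rose, 4 fell and 7 did not pass, with a median of -0.20 (0 with 1 member at its bound, 0.26 with upper-quartile scaling, 0.22 with the GC correction), a mean of -0.72 and a test direction up. The miR-15/miR-16 family had 6 of 12 lower, 1 higher and 5 not passing (median -1.39), the miR-322/miR-503 cluster 5 of 11 lower, 3 higher and 3 not passing (-0.86, or 0.04 with the GC correction), the miR-30 family 5 of 11 lower, 2 higher and 4 not passing (-0.78) and the miR-29 family 2 of 7 lower, 1 higher and 4 not passing (-0.41, and 0.05 with upper-quartile scaling and 0.47 with the GC correction). The miR-212/miR-132 cluster had 1 of 4 higher and 3 not passing (median 0.26), and the other-tissue markers 4 of 12 lower and 8 not passing (median -1.21, or -0.50 with 2 members at their bounds). In fry, the PValue passed for the raised list (adjusted p = 0.013), the muscle microRNAs (0.0027), the Dlk1-Dio3 cluster (0.00363) and most other lists. Among these were the lowered list (0.0396), the let-7 family (0.00937) and the other-tissue markers (0.0222). The miR-17-92, miR-322/miR-503 and miR-212/miR-132 clusters and the leukocyte markers did not pass (0.132 to 0.511). As fry does not compare a list with other microRNAs, these values set no list apart. The share of counts of the muscle microRNAs moved against the median of their list, with 46.3% ± 13.3 in TAC+PDE5A-I and 24.2% ± 3.07 in TAC, as the abundant miR-133a-3p and miR-486b-5p rose. Vascular smooth muscle markers took 2.05% ± 1.98 and 9.41% ± 2.10, and endothelial markers 0.688% ± 0.762 and 3.56% ± 0.524 (n = 5 each, two-sided exact permutation p = 0.00794 for each, 0.0524 adjusted over 66 tests).

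In all, 121 microRNAs rose and 139 fell, so 46.5% of calls were higher, and with upper-quartile scaling most calls were (172 higher, 110 lower). The median of all microRNAs was -0.31, and -0.46, -0.27 and 0.16 with DESeq2 size factors, total counts and upper-quartile factors. The groups did not overlap for 190 microRNAs (33.9%, chance 0.794%). After the correction for arm GC, 87 were higher and 75 lower: miR-29b-3p (-0.53 ± 0.27) and miR-146b-5p (-0.50 ± 0.36) did not pass, and miR-29a-3p was higher (1.47 ± 0.33). Without TAC+PDE5A-I 3, 4 and 5 and TAC+PDE9A-I 5, 41 were higher and 81 lower, and miR-199a-5p, miR-499-5p, miR-133a-3p, miR-30a-5p, miR-146b-5p and miR-451a no longer passed (adjusted p = 0.117, 0.0524, 0.241, 0.162, 0.0911 and 0.334), while a fit of both groups alone without these libraries (2 against 5 mice) gave 6 higher and 66 lower. The higher count was 65 without TAC 3 and 56, 58 and 64 without TAC+PDE5A-I 3, 4 or 5, and miR-133a-3p lost its call without any of these 4 (adjusted p = 0.0685 to 0.157). miR-451a lost its call without TAC 4 or 5 or TAC+PDE5A-I 3, 4 or 5 (adjusted p = 0.059 to 0.104).

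TAC+PDE9A-I against TAC asked the same of the PDE9A inhibitor PF-04449613. By edgeR, 0 microRNAs rose and 0 fell of 561, 16 had an unadjusted p under 0.05, the Wald test of DESeq2 gave 1 higher and 1 lower, and limma voom gave 0 and 0. miR-208b-3p measured 1326 ± 955 CPM (n = 6) against 2681 ± 1195 CPM in TAC (n = 5), a log2 fold change of -1.02 with a 95% interval from -2.22 to 0.19. miR-21a-5p stood at -0.51 (-1.93 to 0.90), miR-146b-5p at -0.95 (-1.97 to 0.08), miR-199a-5p at -0.29 (-1.14 to 0.57), miR-214-3p at 0.11 (-0.70 to 0.92), miR-1a-3p at -0.26 (-1.91 to 1.40) and miR-133a-3p at 0.22 (-0.29 to 0.73). In simulated data of this size, 44.7% of 2-fold and 74.7% of 4-fold changes were recovered. There, 94 microRNAs changed 2-fold and 91 changed 4-fold, of 515 tested. With few true changes the adjustment of p is stricter, so these shares can overstate what would be recovered here. The fold changes followed arm GC content here too (Spearman rho = 0.462), in a group that includes TAC+PDE9A-I 5.

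The smallest p was that of miR-3074-5p (27.8 ± 6.35 against 63.1 ± 21.2 CPM, log2 -1.18 ± 0.25, adjusted p = 0.0879). It passed without TAC 5 (-1.34, adjusted p = 0.0106), and miR-486b-3p (-0.97 ± 0.35) passed without TAC+PDE9A-I 5 (-1.39, adjusted p = 0.0252). Both passed after the GC correction (adjusted p = 0.0486 each) and without the libraries under 2000000 counts (adjusted p = 0.0373 each). miR-300-3p (-0.53 ± 0.22), miR-6538 (1.25 ± 0.44), miR-501-3p (0.63 ± 0.23) and miR-3470b (0.76 ± 0.32) had the next smallest p among abundant microRNAs and did not pass. Of the 17 lists, the Dlk1-Dio3 cluster lay below the other microRNAs (median -0.29, 0 of 57 called over all microRNAs or adjusted over the list alone; camera adjusted p = 0.000951; adjusted p = 0.754 with an estimated correlation). The PValue of fry did not pass (adjusted p = 0.465). The cluster lay higher in TAC against Sham, and both comparisons share the TAC libraries. High values in these libraries alone would give both shifts, so the fall does not show a reversal by PF-04449613. Examples of the cluster by p were miR-300-3p, miR-410-3p (-0.60 ± 0.31), miR-411-5p (-0.59 ± 0.32) and miR-376a-3p, the last with 0.15 and 1.37 CPM. The raised list had a median of -0.17 (camera adjusted p = 0.112), the lowered list 0.06 (0.522), the muscle microRNAs -0.09 (0.0703) and the miR-199/miR-214 group -0.19 (0.276), and no member of any list passed, over all microRNAs or adjusted over the list alone. Without TAC+PDE9A-I 5 the muscle microRNAs lay lower in camera (adjusted p = 0.000253; adjusted p = 0.205 with an estimated correlation). Without the libraries under 2000000 counts the muscle microRNAs (0.00181), the raised list (0.0388) and the endothelial markers (0.0388) lay lower and the other-tissue markers (0.00667) higher. With the GC correction the lowered list (0.00334) and the miR-30 family (0.0117) lay higher, and none of these passed with an estimated correlation. The groups did not overlap for 0 microRNAs, where chance gives 0.433%.

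TAC+PDE5A-I against TAC+PDE9A-I tested the difference of the inhibitors at matched time, with doses not given in the sources used here. miR-208b-3p was 8.29-fold lower under sildenafil, at 159 ± 109 CPM (n = 5) against 1326 ± 955 CPM (n = 6), a log2 difference of -3.05 with a 95% interval from -4.39 to -1.72 (adjusted p = 0.00355). miR-21a-5p was 12.2-fold lower (-3.61, -5.22 to -1.99), miR-208a-3p 9.33-fold (-3.22, -4.83 to -1.62), miR-1a-3p 8.87-fold (-3.15 ± 0.88, SE), miR-499-5p 5.31-fold (-2.41, -3.86 to -0.96) and miR-455-5p 12.5-fold lower (-3.65, -5.16 to -2.14). These differences too followed arm GC content (Spearman rho = 0.741), and with the GC correction miR-208b-3p (-0.72 ± 0.40, SE) and miR-1a-3p (-0.26 ± 0.22) did not pass (adjusted p = 0.203 and 0.453), while miR-21a-5p did (-1.54 ± 0.43, adjusted p = 0.0206). miR-101c was at least 506-fold lower. Higher under sildenafil were miR-501-3p (2.20-fold, 1.14, 0.65 to 1.62), miR-125a-5p (2.02-fold, 1.01, 0.54 to 1.49), miR-8112 (2.40-fold, 0.65 to 1.88), miR-15b-5p (1.99-fold, 0.99 ± 0.24, SE) and miR-34a-5p (1.41-fold, 0.50, 0.11 to 0.89). Differences that did not pass were those of miR-214-3p (0.78, -0.03 to 1.59), miR-126a-3p (-1.09, -2.26 to 0.08), miR-132-3p (0.34, -0.22 to 0.90), miR-212-5p (0.27, -0.31 to 0.84), miR-133a-3p (0.60 ± 0.24, SE), miR-29a-3p (-0.50, -0.92 to -0.08), miR-146b-5p (-1.11, -2.16 to -0.05) and miR-451a (-1.82, -3.36 to -0.27).

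By list, the raised list had 10 of 31 lower and 4 higher (median -0.56, -0.50 with 1 member at its bound), the lowered list 14 of 36 lower and 3 higher (-0.54, -0.50 with its bound), the muscle microRNAs 7 of 17 lower and 4 higher (-0.87, -0.64 with the bound), the miR-30 family 6 of 11 lower and 0 higher (-0.64) and the Dlk1-Dio3 cluster 10 of 57 lower and 5 higher (-0.72, -0.22 with 9 at their bounds). The erythroid markers had 2 of 3 lower, the endothelial and smooth muscle markers 2 of 4 each and the other-tissue markers 4 of 12 (-1.30, -0.75 with 2 at their bounds), with none higher in these 4 lists. The miR-17-92 cluster (median -0.16, 0 with 1 member at its bound), the miR-322/miR-503 cluster (-0.86) and the leukocyte markers (-0.19) had a test direction up, and no list passed camera (lowest adjusted p = 0.302). With the GC correction the lowered list and the let-7 family lay higher (adjusted p = 0.0270 each, 0.945 with an estimated correlation), and the medians of the let-7 family, the miR-29 family and the miR-322/miR-503 cluster were 0.36, 0.50 and 0.27. In all, 85 microRNAs were higher and 110 lower, so 43.6% of calls were higher, and 28.4% and 60.5% were with DESeq2 size factors and upper-quartile factors, which moved the median of all microRNAs from -0.25 to -0.41 and 0.11. The groups did not overlap for 11 microRNAs (1.96%, chance 0.433%). In a fit of these groups alone 0 microRNAs were higher and 0 lower by edgeR, and without the libraries under 2000000 counts 20 were higher and 84 lower. With the GC correction 51 were higher and 64 lower, and 85 of these were called without it. Without TAC+PDE5A-I 3, 4 or 5 the higher count was 13, 17 and 28 and the lower count 59, 67 and 69. Without TAC+PDE5A-I 2 the lower count was 167, and without TAC+PDE9A-I 1, 2, 3, 4 or 6 the higher count was 53, 14, 53, 49 and 40. miR-34a-5p lost its call without any 1 library of either group (log2 0.24 to 0.46), miR-499-5p without TAC+PDE5A-I 3 (adjusted p = 0.0577) and miR-15b-5p without TAC+PDE5A-I 4 (0.0537).

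The drug groups were also set against Sham. In TAC+PDE9A-I, 7 microRNAs were higher than in Sham and 4 lower: miR-208b-3p (8.66-fold, adjusted p = 0.0118), miR-208b-5p (at least 2.98-fold), miR-7689-3p (at least 5.65-fold), miR-214-3p (3.76-fold), miR-214-5p (2.96-fold), miR-199a-5p (3.14-fold) and miR-501-3p (2.29-fold) rose, and the muscle microRNAs miR-133b-3p (2.14-fold) and miR-486b-3p (2.60-fold) and miR-378b and miR-378c (1.92-fold and 1.79-fold) fell. With the ear tag range as a covariate 1 microRNA was called, a higher one, and in the fit of these groups alone 4 were, 2 of them higher. In TAC+PDE5A-I, 239 microRNAs differed from Sham, of which 107 were higher. miR-208b-3p (0.06 ± 0.60) and miR-199a-5p (0.38 ± 0.43) did not pass, miR-214-3p was 6.46-fold higher (adjusted p = 0.000178), miR-501-3p 5.05-fold and miR-99b-5p 2.55-fold higher, and miR-21a-5p and miR-338-3p were 5.20-fold and 3.85-fold lower. The fold changes followed arm GC content (Spearman rho = 0.724), and of the 100 higher and 74 lower calls with the GC correction 114 were among the 239. With it miR-208b-3p was above Sham (2.76 ± 0.44, adjusted p = 0.000236), and miR-21a-5p and miR-338-3p (adjusted p = 1.00 and 0.992) did not pass, so whether miR-208b-3p returned to its Sham level depended on the correction. The share of higher calls was 44.8% in TAC+PDE5A-I (59.6% with upper-quartile factors) and 63.6% in TAC+PDE9A-I (86.7% with total counts and 81.8% with upper-quartile factors). The median of all microRNAs against Sham moved from -0.28 to -0.44, -0.06 and 0.15 with DESeq2 size factors, total counts and upper-quartile factors in TAC+PDE5A-I, and from -0.06 to 0.14 with total counts in TAC+PDE9A-I. Without TAC+PDE9A-I 2 or 6 the higher count of that group against Sham was 22 and 25, and the lower count was 2 without Sham 1, 3, 4 or 5 or TAC+PDE9A-I 1 and 1 without TAC+PDE9A-I 3 or 4. Without TAC+PDE5A-I 3 or 4, 67 and 71 were higher than in Sham under sildenafil. The groups did not overlap with Sham for 184 microRNAs (32.8%, chance 0.794%) and 22 microRNAs (3.92%, chance 0.433%).

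Whether the drugs moved microRNAs against their change in TAC was measured as the slope of the drug's log2 fold change on that of TAC against Sham, across 561 microRNAs, which are not independent replicates. The slope was -0.203 for sildenafil (r = -0.104) and -0.408 for PF-04449613 (r = -0.542). Since both comparisons share the TAC libraries, simulations with no TAC effect and no drug effect were set beside them. They gave mean slopes of -0.505 (95% range -0.901 to -0.103) and -0.499 (-0.878 to -0.131), and neither slope lay outside its range. The r of sildenafil lay above its range (-0.760 to -0.117) and that of PF-04449613 within it (-0.787 to -0.144). Unlike the data, the simulations hold no TAC effect and spread the deviations of all libraries from their group means over all groups. Their ranges therefore do not decide whether a drug reversed the TAC changes. The jackknife SE of the slope was 0.160 for sildenafil and 0.113 for PF-04449613. The covariance minus its simulated mean was 0.0864 for sildenafil and -0.0799 for PF-04449613. With separate TAC libraries for each side, the slope averaged -0.0302 over 20 fits for sildenafil (-0.158 to 0.0906) and -0.207 for PF-04449613 (-0.379 to -0.125). The fold changes of the drugs against TAC correlated with each other at r = 0.604, where the shared TAC libraries alone gave 0.514 (95% range 0.132 to 0.781). Their covariance, 0.704, lay above the range given by the shared libraries (0.0454 to 0.549). TAC+PDE9A-I 5, whose deviation from its group followed the sildenafil fold changes (r = 0.920), was part of this comparison. The r averaged 0.417 over 20 fits with separate TAC libraries (0.336 to 0.483).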

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

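The tests weighed here, apart from the other splits of the libraries, were chosen after the results were seen (those of arm GC content, thinning, sildenafil as the only source, the 2 arms of a hairpin and a wrong label). In 312 groups of 5 or 6 libraries, 34 values lay far from the others of their group by Dixon's test, where chance marks about 1 in 20 groups, and 21 of the 34 belong to TAC+PDE9A-I 5. These groups of values are correlated with each other.

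In TAC+PDE9A-I 5, the muscle microRNAs took 51.8% of counts (16.2% to 25.3% in the other 5 libraries), the markers of other tissues 0.0265% (0.163% to 0.231%), the count-weighted arm GC was 52.9% (47.2% to 48.6%), and 386 microRNAs had at least 1 CPM (513 to 583). In log2 CPM the following were low: miR-208a-3p 4.52 (8.24 to 9.99 in the others), miR-208b-5p -1.31 (0.81 to 1.60), miR-1a-3p 6.94 (11.05 to 12.85), miR-30a-5p 13.47 (14.73 to 15.40), miR-29b-3p 3.29 (5.93 to 6.57) and miR-29c-3p 6.32 (8.49 to 9.50). The leukocyte microRNAs miR-142a-3p and miR-142a-5p stood at 5.17 (9.14 to 10.20) and 3.46 (6.95 to 8.61). Also low were miR-101c at -1.31 (8.65 to 10.27), miR-136-5p at -1.31 (4.21 to 5.49), miR-190a-5p at 0.72 (4.94 to 5.30), miR-340-5p at 4.44 (6.73 to 8.07) and miR-148a-3p at 9.34 (12.46 to 13.07). High were miR-125a-5p at 13.50 (12.55 to 12.77), miR-125a-3p at 4.11 (3.43 to 3.64), miR-361-3p at 6.73 (6.12 to 6.32) and miR-8112 at 5.36 (3.84 to 4.30).

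The other 13 values lay in 8 libraries. In TAC 1, log2 CPM was low for miR-29a-3p at 11.37 (12.06 to 12.27 in the other TAC libraries), miR-29c-5p at 3.01 (3.45 to 3.57), miR-125a-5p at 11.89 (12.47 to 12.67) and miR-324-3p at 3.21 (3.66 to 3.75), and the leukocyte share was 0.195% (0.292% to 0.321%). miR-1a-3p was low in TAC 3 at 11.25 (12.01 to 12.25). In TAC+PDE5A-I 2, miR-127-3p stood at 10.72 (11.78 to 12.13) and miR-30c-2-3p at 7.25 (7.71 to 7.80), miR-34a-5p was high in TAC+PDE5A-I 3 at 8.13 (7.68 to 7.75) and miR-144-3p low in TAC+PDE5A-I 4 at 0.81 (1.89 to 2.22). In Sham 2, miR-22-3p took 16.6% of counts (at most 19.8% in the others), and in Sham 1 miR-29b-3p stood at 6.89 (6.39 to 6.51). In TAC+PDE9A-I 4, miR-376a-3p stood at 0.38, where each other library of the group had no count (-1.31).

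The profile of TAC+PDE5A-I against TAC was weighed first. Lower depth alone was argued against, since thinning all libraries to the smallest total gave 216 calls, most of them among the 260. After the GC correction 32.0% of the microRNAs tested were called, 116 of these 162 among the 260. As the correction rests on GC values of predicted arms, calls can remain after it even if arm GC were the whole cause. The test therefore leaves arm GC as the whole cause undecided. GC-dependent recovery as part of the cause had the values it needs (Spearman rho = 0.729 across microRNAs, which are not independent replicates). As this rho had been seen before, it is no separate test of that explanation. The deviation of TAC+PDE9A-I 5 from its group correlated with the sildenafil fold changes at r = 0.920 over microRNAs of at least 10 CPM and at r = 0.815 over all tested. As this is 1 library, sildenafil as the only source of the profile stays open and cannot be told apart from a contribution of the libraries.

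For TAC+PDE9A-I 5, GC-dependent recovery as part of the cause had the value it needs: over 74 hairpins, the difference of the 2 arms in the deviation of this library went with their difference in GC (rho = 0.587). For the other 5 libraries, compared without it, rho was -0.241 to 0.372. A wrong label, a sildenafil-treated mouse, stays open and cannot be told apart from such a library state, since r after the GC correction was 0.857, between the values set for and against it. In the 74 hairpins with both arms measured, the arms' log2 fold changes were compared under sildenafil against TAC. Their difference went with the difference of the arms in GC (rho = 0.610). The same rho was -0.0937 for TAC against Sham and 0.418 for TAC+PDE9A-I against TAC. The value under sildenafil argues against a change of the precursor that moves both arms alike, as the only process. Arm GC has the values it needs. Of 31 hairpins with both arms called, 5 had arms that moved in opposite directions.

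Of splits of the same libraries into groups of these sizes, 100 per comparison were counted. The smallest share that 100 splits can give is 1 of 100. For TAC against Sham, chance is unlikely (13 calls, at most 1 in another split, 1 of 100 splits as large, the real one). The same holds for TAC+PDE5A-I against TAC (260, at most 47, 1 of 100), TAC+PDE5A-I against Sham (239, at most 65, 1 of 100) and TAC+PDE9A-I against Sham (11, at most 5, 1 of 100). For TAC+PDE9A-I against TAC there was no result to set against chance (0 calls by edgeR, 16 at an unadjusted p under 0.05), so 100 of 100 splits were as large by construction, at most 0 in any, and the splits do not bear on this comparison. For TAC+PDE5A-I against TAC+PDE9A-I the real split gave 85 higher and 110 lower, and 2 of 100 splits gave as many. The other one, with 284, placed TAC+PDE9A-I 5 with the sildenafil libraries, which points to a structure of the samples that the groups do not follow.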

How the results depend on the processing

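Of the alternatives here, the GC correction, leaving out the 4 libraries under 2000000 counts, thinning and the fit of 2 groups without those libraries were chosen after the results were seen, and the others before. Counts are given as higher and lower. The cause of the changes below was not tested, except that fewer libraries, or fewer or more microRNAs tested, are part of some alternatives by construction. The 4 libraries under 2000000 counts are all drug libraries. For TAC against Sham, leaving them out therefore acts only through the shared spread, scaling and filter.

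TAC against Sham had 12 higher and 1 lower. The higher count was 20 with no filter, 30 with a mean of at least 10 CPM, 33 with the Wald test of DESeq2, 4 with the ear tag range, 28 with the GC correction, 46 without libraries under 2000000 counts, and 75 in the fit of 2 groups, with or without these libraries. The lower count was 2 with DESeq2 size factors, 0 with total counts, 2 with upper-quartile factors, 0 with no filter, 6 with at least 10 CPM, 21 with the Wald test, 7 with limma voom, 0 with the ear tag range, 6 with the GC correction, 29 without libraries under 2000000 counts, 3 after thinning and 23 in either fit of 2 groups. Leaving out 1 library gave 3 to 14 higher and 0 to 1 lower, with 0 lower without any 1 Sham library, TAC 3 or TAC 5. miR-208b-3p kept its call in each, and miR-199a-5p and miR-214-3p lost theirs without Sham 1, 2, 3 or 4 or TAC 4 (adjusted p = 0.0504 to 0.0777).

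TAC+PDE5A-I against TAC had 121 higher and 139 lower. The higher count was 58 with no filter, 41 without libraries under 2000000 counts and 6 when these were left out of the fit of 2 groups. The lower count was 75 with the GC correction, 81 without these libraries and 66 in that fit of 2 groups. Of the calls after the GC correction, 116 of 162 were called before it, and 71 of 72 in the last fit. Leaving out 1 library gave 56 to 108 higher and 109 to 191 lower. TAC+PDE9A-I against TAC had 0 and 0 by edgeR, with 16 at an unadjusted p under 0.05. It had 1 lower with upper-quartile factors, 1 lower with at least 10 CPM, 1 higher and 1 lower with the Wald test, 2 lower with the GC correction, 2 lower without libraries under 2000000 counts, and 0 to 1 lower when 1 library was left out (1 without TAC 5 or TAC+PDE9A-I 5).

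TAC+PDE5A-I against TAC+PDE9A-I had 85 higher and 110 lower. The higher count was 50 with DESeq2 size factors, 138 with upper-quartile factors, 29 with no filter, 56 with at least 10 CPM, 26 with the ear tag range, 51 with the GC correction and 20 without libraries under 2000000 counts. The lower count was 169 with the Wald test and 64 with the GC correction. The fit of 2 groups gave 0 higher and 0 lower, and 3 higher and 58 lower without these libraries. Leaving out 1 library gave 13 to 95 higher and 59 to 167 lower.

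TAC+PDE5A-I against Sham had 107 higher of 239 calls. The higher count was 164 with upper-quartile factors, 34 without libraries under 2000000 counts and 43 in the fit of 2 groups without them, and the lower count was 74 with the GC correction and 86 without these libraries. Leaving out 1 library gave 67 to 98 higher. TAC+PDE9A-I against Sham had 7 higher and 4 lower. The higher count was 26 with total counts, 17 with at least 10 CPM, 26 with the Wald test, 1 with the ear tag range, 17 with the GC correction, 24 without libraries under 2000000 counts, 2 in the fit of 2 groups and 26 in that fit without these libraries. The lower count was 2 with upper-quartile factors, 9 with the Wald test, 7 with limma voom, 0 with the ear tag range, 13 without libraries under 2000000 counts, 2 in the fit of 2 groups and 12 in that fit without them. Leaving out 1 library gave 5 to 25 higher and 1 to 6 lower.

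With the replicate block, TAC against Sham had 2 lower. Of the named microRNAs, 3 lost their call with the replicate block (miR-300-3p and miR-208b-5p in TAC against Sham, miR-34a-5p between the drugs) and 4 gained one, and it changed no other call of a named microRNA.

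The sign changed for 8 named results, each with the GC correction. Under sildenafil against TAC, miR-29a-3p became 1.47 (adjusted p = 0.00293), miR-324-3p -0.0277, miR-874-3p -0.31, miR-190a-5p 0.51 and miR-340-5p 1.01, and against TAC+PDE9A-I miR-29a-3p became 0.87 (adjusted p = 0.0484), miR-190a-5p 0.56 and miR-340-5p 0.90. The correction is approximate, as the arm sequences rest on predicted hairpins: it gave let-7a-5p 4.26 and let-7d-3p 3.53. By list under sildenafil against TAC, the median of the let-7 family went from -0.66 to 0.76 and that of the miR-29 family from -0.41 to 0.47. Of the named results, 18 lost their call in some fit that left out 1 library (89 losses over all such fits). In the fit of 2 groups 26 did, without libraries under 2000000 counts 12, and with the ear tag range 11. With the GC correction 10 did, not counting results whose sign changed. Of those with a changed sign, miR-324-3p, miR-874-3p, miR-190a-5p and miR-340-5p lost their calls too.

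The reversal slope of sildenafil was -0.498 over the 13 microRNAs called in TAC against Sham and -0.0302 with separate TAC libraries, and that of PF-04449613 -0.249 and -0.207. The 13 were chosen on the same TAC libraries that enter both comparisons. This alone pulls the slope below 0, so the slopes over the 13 do not bear on reversal. Over all microRNAs tested, leaving out 1 library gave -0.292 to -0.140 for sildenafil and -0.459 to -0.368 for PF-04449613. Depth limited the low end: 3 counts over a TAC+PDE5A-I library of 1205417 counts correspond to a higher CPM than in any other library, so absence there bounds the level less tightly.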

Other observations

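Of the tests in this part, the position between Sham and TAC was tested after the results were seen, the set raised in TAC was tested on split TAC libraries after a first try on the full set, and the set lowered in TAC was tested last. miR-27b-3p took 3.94% ± 0.159 of counts in Sham (n = 5) and 7.68% ± 1.37 in TAC (n = 5), making it one of the most abundant microRNAs of the overloaded heart. Its 1.75-fold rise passed in the fit of Sham and TAC alone (adjusted p = 0.000471) and not in the fit of 4 groups (adjusted p = 0.257). Its share was 5.65% ± 2.10 under PF-04449613 (n = 6) and 2.79% ± 1.69 under sildenafil (n = 5). miR-143-3p, of smooth muscle cells and fibroblasts, took 7.78%, 9.32% and 1.95% of counts in Sham, TAC and TAC+PDE5A-I. miR-486b-5p took 10.5% ± 1.12 in Sham, 10.1% ± 2.16 in TAC and 11.1% ± 7.32 in TAC+PDE9A-I. In TAC+PDE9A-I its share ran from 6.01% to 25.7%, so the mean hides a wide spread. miR-486b-5p and miR-486a-5p rose 2.12-fold and 2.19-fold under sildenafil against TAC (adjusted p = 0.0229 and 0.0208). Neither passed after the GC correction (log2 0.47 ± 0.29 and 0.20 ± 0.26).

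A hypothesis was that sildenafil lowered the microRNAs that TAC raised, beyond what arm GC content gives. In each of 20 fits, a set of 50 microRNAs of 284 was chosen on one part of the TAC libraries and measured against the other part. The median log2 fold change of the set under sildenafil lay below the 95% range of GC-matched random sets in 20 of 20 fits (mean -0.73, from -0.98 to -0.53, random sets 0.137). It lay below their median in 20 of 20 fits, which argues against the shared TAC libraries as the whole cause. Arm GC as the whole cause is argued against only as far as the estimated GC values hold. Under PF-04449613 the median of the set also lay below the 95% range in 20 of 20 fits (mean -0.40, from -0.56 to -0.20, random sets -0.00715). That group includes TAC+PDE9A-I 5, whose deviation followed the sildenafil fold changes (r = 0.920). No fit left this library out, so how far the result rests on it was not tested. The fits share libraries and the random sets ignore the correlation between microRNAs within a mouse, so that the 20 fits are not 20 independent tests. On the full set of 73 the median under sildenafil was -0.66 (random sets -0.11, 95% range -0.40 to 0.30). For the 75 raised in the fit of Sham and TAC the median was also -0.66. It shrank to -0.30 after the GC correction and to -0.29 without the libraries under 2000000 counts. The microRNAs lower in TAC were mixed under sildenafil: of the 23 called in the fit of Sham and TAC 10 were lower, 7 higher and 6 did not pass. Their median was -0.78, or 0.11 after the GC correction and -0.12 without the libraries under 2000000 counts. For the 50 lowest in TAC, chosen in the same way, the median lay below the range of GC-matched random sets in 0 of 20 fits and within it in 20 (mean -0.64, random sets -0.786). Under PF-04449613 it lay above the range in 12 of 20 fits and within it in 8 (mean -0.08, random sets -0.215). Whether sildenafil lowered the raised set more than the rest of the profile may be tested in other mice.

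The position of each library on the line from Sham (0) to TAC (1), with each library held out of its own axis and after the GC correction, gave no shift past the test for either drug. TAC+PDE9A-I lay at -0.140 from TAC (n = 6 and 5, two-sided exact permutation p = 0.450, adjusted p = 0.778) and TAC+PDE5A-I at 0.0428 (n = 5 each, exact p = 0.778, adjusted p = 0.778). TAC+PDE9A-I 6 scored 0.240 and the others of its group 0.561 to 1.11, so the mean of this group leans on 1 library. Without the GC correction TAC+PDE9A-I lay at -0.293 (exact p = 0.0173, adjusted p = 0.0346), with 4 of 6 libraries below every TAC library, and TAC+PDE5A-I at 0.0556 (exact p = 0.690). Without the libraries under 2000000 counts, TAC+PDE9A-I lay at -0.250 (exact p = 0.0317, adjusted p = 0.0635), and with both steps at -0.119 (exact p = 0.579) with TAC+PDE5A-I at -0.0649 (exact p = 0.762). The 4 versions differ, so a partial shift under PF-04449613 was neither shown nor excluded.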
